A study of Mus musculus with 8 samples.

How the data were processed

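RNA from mouse colon was sequenced for 8 mice with dextran sulfate sodium (DSS) colitis, 4 without and 4 with Alistipes putredinis (AP). Per the labels' protocols, total RNA was purified with an RNeasy column kit, and libraries of messenger RNA were made with a SMARTer kit. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the mouse genome build GRCm38.p6, without the role of each. The deposited values are estimated counts per gene and library, not normalized to depth: between 10.7% and 11.5% of the values in each library were not whole numbers, as RSEM's sharing of reads among genes gives. Whether counting used the strand of the reads is not given in the sources used here. Totals ran from 16089081 to 17104290 estimated counts per library, which sets the precision, and 3 counts were taken as the floor of detection.

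The table paired gene symbols with gene IDs for 18806 genes, of which 18750 were found in the RefSeq gene table of GRCm38.p6, the source of all coordinates given. No immunoglobulin segment or mitochondrially encoded gene was listed, and 6 haemoglobin genes took at most 0.0140% of the counts of any library. Pairs of libraries of 1 group had Spearman correlations across genes of 0.977 to 0.989 in DSS and 0.984 to 0.994 in DSS+AP, and pairs across groups 0.953 to 0.988. The chi-square statistic per gene was at least 11.7 for every pair within a group, so no library was a copy of another.

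Counts were rounded to whole numbers, filtered with filterByExpr, scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test with robust estimation compared DSS+AP with DSS without covariates, and Benjamini-Hochberg adjustment ran over the 14578 genes tested with a threshold of 0.05. The biological coefficient of variation was 0.200. Standard errors of log2 fold changes were taken from the estimate and its F statistic. CPM values use the TMM-scaled totals of the tested genes, and log2 CPM a prior count of 2. Fixed gene lists, 35 in number with 741 entries of which 640 were tested, covered the pathways and cell types of inflamed colon and of tissues that a piece of colon could carry along. Some lists share members, such as Il33 (cytokines and fibroblasts), Thy1 (T cells and fibroblasts) and Ccl22 (chemokines and dendritic cells), so they are not independent. The 33 lists with at least 5 tested members were compared with the other genes by camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. No list held with the correlation estimated per list. Counts of members past the threshold are given both over all genes and adjusted over the list alone. Principal components used the 500 most variable genes, and differences of single values between groups were tested with exact two-sided permutation over 70 assignments.

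Genes are named in the text by a rule. It takes the 10 higher and the 10 lower genes with the largest fold change among those past the threshold with a mean log2 CPM of at least 0 and no overlap between groups, leaving out predicted genes and RIKEN clones. It adds up to 3 members of each list that passed or holds a gene past the threshold, those past it first and by smallest p, the most abundant member of any other pathway list, and Foxp3, Il10, Tnf, Il6, Il1b and Ifng. The rule gave 127 genes, of which 125 are described and the rest not analysed further here, and 25 more are named that were chosen after their values were seen. The grouping, tests, lists, naming rule and 21 alternatives were set before the data were examined, and the Hox, cholesterol and glucocorticoid lists and 4 alternatives were chosen after seeing the data. The alternatives were other scaling factors, other low-count filters, no robust estimation, the replicate number as a block, leaving out each library, leaving out haemoglobin genes, DESeq2 1.42.0, limma-voom with quality weights, an estimated correlation, fry, other settings of the principal components, 3 covariates and a test against a 1.5-fold change.

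The steps were tested on simulated data with the means and depths of these libraries. Genes were drawn independently and the simulated lists were random. The simulation therefore cannot show how often camera falsely calls lists whose members vary together, as members of the real lists did. Over 14578 genes with 200 changed, edgeR recovered 22.4% of those changed 1.5-fold, 71.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls (4.51% of calls), and camera called 10 of 10 moved lists and 0 of 10 unmoved ones. Exons were compared with a genome annotation of the same build. Among the named genes, Pakap, Foxp3 and Ifng share at least 10% of their exon bases with another gene on their strand, and Mmp7, Wfdc12, Cxcl16, Jam3, Hspa1a, Txndc5, Hopx, Alox5ap, Ckm, Alas2 and Foxp3 with a gene on the other strand. Their counts are uncertain. Figures were drawn with matplotlib 3.10.9.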

Results

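Colon RNA was sequenced from 8 mice with colitis, 4 in each of 2 groups. Dextran sulfate sodium (DSS), a polysaccharide that injures the colon epithelium, caused the colitis in all of them, and the second group also received Alistipes putredinis (AP), an anaerobic bacterium of the gut (the DSS+AP group). Each library came from a separate mouse picked at random from its group. No mouse without DSS was in the series, so no level could be set against healthy colon. The deposited values were estimated counts for 18806 genes, with totals between 16089081 and 17104290 per library. Group means of the totals did not differ beyond their spread (exact two-sided permutation p = 0.829, n = 4 each). At this depth, 3 counts corresponded to between 0.167 and 0.186 CPM (counts relative to the scaled library total), and this floor covers counting error only. Between 16555 and 17016 genes had a count above 0, and the 10 most abundant genes took between 5.64% and 8.95% of each library.

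The comparison asked how colitic colon differed when the bacterium was given, in a study whose title speaks of immune tolerance. Genes of inflammation, of neutrophils, macrophages, dendritic cells and B cells, and of the connective tissue, vessels and nerves of the gut wall were lower in DSS+AP colon. Genes of crypt stem cells were higher. So by camera were those of dividing cells and of the type I interferon response, but fry, a rotation test, called neither (adjusted p = 0.0707 and 0.163). With an estimated correlation 0 of the 33 lists tested passed, higher or lower (smallest adjusted p = 0.407). Zbtb16, a zinc finger transcription factor of innate-like lymphocytes on chromosome 9 (gene 235320; 48651797 to 48836225, GRCm38.p6), had the smallest edgeR adjusted p of all genes, 0.00176, and fell from 57.6 ± 17.6 to 4.24 ± 0.685 CPM (mean ± SD, n = 4 per group). Ptx3, which encodes an acute-phase pentraxin (chromosome 3, 66219887 to 66225806), fell the most among the genes the naming rule took, with a log2 fold change of -5.90 ± 0.89 (SE; edgeR adjusted p = 0.00385). Lgr5, the receptor that marks crypt stem cells (gene 14160; chromosome 10, 115450314 to 115587780), rose the most among them, from 2.19 ± 2.21 to 14.6 ± 3.74 CPM. All fold changes are DSS+AP over DSS on the log2 scale with their SE, from 4 mice per group. The other named genes with large falls were A2m at -4.33 ± 0.85, which encodes a protease inhibitor of plasma, Chil1 at -4.19 ± 0.70, the carboxylesterase gene Ces2f at -3.86 ± 0.93, the complement receptor gene Cr2 at -3.86 ± 0.88, Wfdc12 at -4.89 ± 1.15, Pakap at -3.77 ± 0.86, Slc37a2 at -3.88 ± 1.03 and Itih4 at -3.85 ± 1.01. In DSS+AP the means of Wfdc12, A2m and Itih4 were 0.0880, 0.176 and 0.161 CPM, at or under the floor of 3 counts, so the sizes of their falls are uncertain. Single libraries were also under 3 counts for Ptx3 (1 in DSS+AP 3, 2 in DSS+AP 4) and Pakap (0 in both). So were Chil1 (2) and Cr2 (1) in DSS+AP 3, and Ces2f was at 3 to 5 counts in DSS+AP. The sizes of these falls, that of Ptx3 included, are uncertain as well. Those with large rises included Mal at 2.48 ± 0.64, the gastric-type mucin gene Muc6 at 2.26 ± 0.55, the cardiac actin gene Actc1 at 2.01 ± 0.43, the meiotic cohesin gene Rec8 at 1.73 ± 0.33 and the neighbouring Apol9b and Apol9a at 2.48 ± 0.39 and 2.06 ± 0.38, which are near-identical copies whose counts are uncertain. Calls were lost for Slc37a2 without DSS+AP 1, DSS+AP 3 or DSS+AP 4 (edgeR adjusted p = 0.0626, 0.0649 and 0.0612), for Itih4 without DSS 3, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (0.0523 to 0.0594), for Mal without DSS 1, DSS 3 or DSS+AP 3 (0.0576, 0.0528 and 0.0533) and for Muc6 without DSS 4 (0.0513). Leaving out 1 library also moved Slc37a2 to -2.21 (without DSS 4), Pakap to -5.95 (without DSS+AP 1), Itih4 to -6.48 and Muc6 to 1.41 (both without DSS+AP 2). Over all alternatives, covariates included, the smallest rises were 0.17 for Actc1, 0.38 for Rec8 and 2.21 for Lgr5. The smallest falls were -0.62 for Wfdc12, -0.90 for Itih4 and -3.48 for Zbtb16.

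Of the 14578 genes tested, 1288 were higher and 2974 were lower in DSS+AP at an edgeR adjusted p under 0.05, and the median log2 fold change over all of them was 0.02. Changes of at least 2-fold among the called genes numbered 106 upward and 1703 downward. In 1572 genes every DSS+AP library lay above every DSS library and in 2852 every one lay below, together 30.3% of the genes. The chance of this for any 1 gene with random labels is 2.86%. Genes vary together, so the difference between these shares does not measure chance. Of the 33 fixed gene lists tested with camera, 4 were higher and 15 lower at an adjusted p under 0.05, and with an estimated correlation 0 were, the smallest adjusted p being 0.407. In that setting 1 list had an unadjusted p under 0.05, and the rotation test fry called 16 of the lists. Leaving out 1 library moved the count of higher genes to 2101 without DSS 2, 847 without DSS 3, 525 without DSS 4, 565 without DSS+AP 3 and 762 without DSS+AP 4. The lower count moved to 1985 without DSS+AP 1, and the higher lists numbered 7 without DSS+AP 2.

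**Figure D1:**
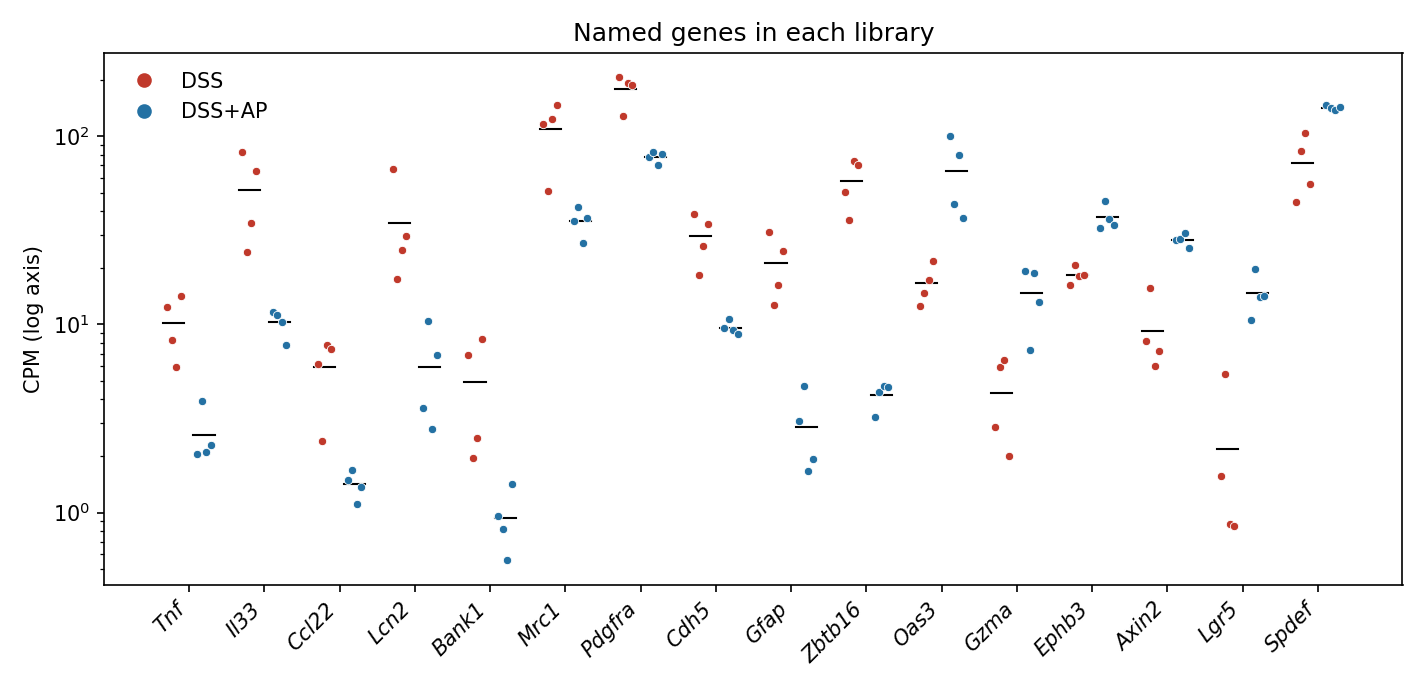
CPM of 16 named genes in each library on a log axis, with 1 point per mouse, DSS in red and DSS+AP in blue, and a bar at each group mean. For Zbtb16 the 4 DSS libraries lie above the 4 DSS+AP libraries, with means of 57.6 and 4.24 CPM, and for Lgr5 they lie below, with means of 2.19 and 14.6 CPM.

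Transcripts of inflammatory cytokines fell in DSS+AP colon. Of the 12 measured members of the cytokine list, 11 were lower and 0 higher over all genes, 12 lower when adjusted over the list alone, and the list's median was -2.07 (camera adjusted p = 2.88e-05; adjusted p = 0.454 with an estimated correlation). Tnf, the gene of tumour necrosis factor (chromosome 17, 35199367 to 35202007), fell from 10.2 ± 3.76 to 2.59 ± 0.889 CPM, a change of -1.97 ± 0.33 (edgeR adjusted p = 0.00451). The alarmin gene Il33 (chromosome 19, 29925113 to 29960718) fell by 2.33 ± 0.37 (0.00412), Il12b by 2.17 ± 0.39 and Il6 by 2.72 ± 0.62 (edgeR adjusted p = 0.0129). Il33 is on the fibroblast list as well. Il12b had 3 to 8 estimated counts per library in DSS+AP, so the size of its fall is uncertain. Il1b, at -1.73 ± 0.54, passed with an edgeR adjusted p of 0.0428, and its call was lost without DSS 1 (0.120), DSS 2 (0.0698), DSS 4 (0.0729), DSS+AP 1 (0.110), DSS+AP 3 (0.0750) or DSS+AP 4 (0.0687). Over the 22 alternatives, covariates included, the smallest falls were -0.16 for Il6 and -0.27 for Il1b. Those of Tnf, Il33 and Il12b were -1.22, -1.26 and -1.36. Chemokine genes fell too, 18 lower and 1 higher of 26 over all genes, and 20 lower and 1 higher adjusted over the list alone. Their median was -1.29 (camera adjusted p = 2.88e-05; adjusted p = 0.407 with an estimated correlation). Cxcl12 changed by -1.08 ± 0.16, Cxcl16 by -0.97 ± 0.15 and Ccl22 by -2.06 ± 0.36. Neutrophil genes were lower in 13 of 14 members, and in 14 adjusted over the list alone, with a median of -2.39 (camera adjusted p = 9.13e-05; adjusted p = 0.488 with an estimated correlation). Among them Csf3r, the receptor of granulocyte colony-stimulating factor, fell by 2.03 ± 0.45, Clec4d by 1.95 ± 0.40 and the decoy receptor gene Il1r2 by 2.65 ± 0.62, or by 1.73 without DSS 1. The antimicrobial list as a whole did not pass (camera adjusted p = 0.137), although 8 of its 21 members were lower, 9 adjusted over the list alone. Without DSS+AP 2 it passed, with a camera adjusted p of 0.0113. Its median was -0.03 and its mean -0.62: Slpi fell by 3.60 ± 0.71, Lcn2 by 2.55 ± 0.52 and Saa3 by 2.24 ± 0.41. The smallest falls of these genes over the alternatives were -1.51, -0.38 and -0.96. In the same libraries the mean of the smooth muscle list was lower in DSS+AP by a log2 difference of -0.94, and that of posterior Hox genes by -1.79.

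Genes linked to regulatory T cells and tolerance were lower rather than higher in DSS+AP. Of 23 measured members, 13 fell and 1 rose over all genes, and 15 were lower and 1 higher adjusted over the list alone, with a median of -0.81 (camera adjusted p = 6.56e-05; adjusted p = 0.448 with an estimated correlation). Tigit, an inhibitory receptor of T and natural killer cells (chromosome 16, 43626137 to 43665125), fell from 38.2 ± 4.12 to 23.4 ± 2.01 CPM (edgeR adjusted p = 0.00350). The estimated counts of Tigit were not whole numbers in any library (573.93 to 720.73 in DSS and 355.87 to 432.78 in DSS+AP). Some of its reads were thus shared with other genes, and its level is uncertain. Entpd1, which encodes the ectoenzyme CD39, fell by 1.44 ± 0.24 and Pdcd1, which encodes PD-1, by 2.32 ± 0.41. Pdcd1 had 3 to 5 estimated counts per library in DSS+AP, near the floor, so the size of its fall is uncertain. Foxp3, the lineage factor of regulatory T cells (chromosome X, 7579676 to 7595243), averaged 1.61 ± 0.309 CPM in DSS and 0.971 ± 0.221 CPM in DSS+AP, and its -0.73 ± 0.25 did not pass (edgeR adjusted p = 0.0581). It passed without DSS 2 (0.0404) and with limma-voom (0.0359). Its count is uncertain, since 18.6% of its exon bases are shared with Flicr on its own strand and 18.7% with genes on the other strand. Il10 was too low to be tested, with a total of 62 estimated counts in DSS, 7 to 27 per library, and 25 in DSS+AP, 4 to 7 per library. Ifng was untested as well, with totals of 12 and 8 and a range from 0 to 6 per library. The T cell list did not pass (median 0.29; camera adjusted p = 0.313): of 20 members 1 was higher and 3 lower, 0 and 3 adjusted over the list alone. It passed as higher without DSS+AP 2 (camera adjusted p = 0.0417). The lower members were Cd4 at -0.82 ± 0.20, Il7r at -1.14 ± 0.28 and Thy1 at -0.68 ± 0.19, of which Thy1 was lost without DSS 1, DSS 3, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (edgeR adjusted p = 0.0605 to 0.0866). Thy1 is on the fibroblast list too. Cytotoxic and natural killer cell genes rose as a list, with a median of 0.85 over 9 members (camera adjusted p = 0.0392; adjusted p = 0.573 with an estimated correlation), of which 2 were higher over all genes and 3 adjusted over the list alone. The scores of this list overlapped, at 1.63 in DSS 3 and 1.27 in DSS+AP 2 (exact two-sided permutation p = 0.0571, n = 4 each). Gzma, the granzyme A gene, rose by 1.76 ± 0.42 (edgeR adjusted p = 0.0157). Nkg7, a cytotoxic granule protein gene, rose by 1.27 ± 0.30. Ctsw, at 1.09 ± 0.37, did not pass (edgeR adjusted p = 0.0534) but did in 7 of 22 alternatives, among them without DSS 3 (0.0207) or DSS+AP 2 (0.0333). The cytotoxic list was lost without DSS 1 (camera adjusted p = 0.0764), DSS 2 (0.108), DSS+AP 1 (0.131) or DSS+AP 3 (0.0568). A minimum of 1 CPM in 4 libraries (camera adjusted p = 0.0837) and fry (fry adjusted p = 0.145) also ended its call. So did the smooth muscle score (median 0.17, camera adjusted p = 0.591) or Hox position (0.38, 0.209) as a covariate. Smooth muscle and posterior Hox means were lower in these libraries by -0.94 and -1.79. Beside the muscle score the tolerance score differed by 0.12 (exact two-sided permutation p = 0.486, n = 4 each).

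Myeloid and B cell transcripts were lower in DSS+AP. Monocyte and macrophage genes fell in 19 of 23 members, also 19 adjusted over the list alone, with a median of -0.95 (camera adjusted p = 9.27e-06; adjusted p = 0.488 with an estimated correlation). Their scores overlapped between groups, at 4.47 in DSS 2 and 4.57 in DSS+AP 2 (exact two-sided permutation p = 0.0571, n = 4 each). Mrc1, the mannose receptor gene of resident macrophages (chromosome 2, 14229414 to 14332023), fell from 110 ± 40.9 to 35.3 ± 6.08 CPM. The Fc receptor gene Fcgr3 fell by 1.31 ± 0.22 and the scavenger receptor gene Msr1 by 1.57 ± 0.27. Dendritic cell genes were lower in 9 of 14 members (11 lower and 1 higher adjusted over the list alone), at a median of -1.05 (camera adjusted p = 4.11e-04; adjusted p = 0.488 with an estimated correlation), with Itgax at -1.12 ± 0.14 and Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, at -2.94 ± 0.54. B cell genes were lower in 14 of 16 members, 15 adjusted over the list alone, at a median of -2.24 (camera adjusted p = 9.13e-05; adjusted p = 0.488 with an estimated correlation). Fcer2a, the low-affinity IgE receptor gene, fell from 2.77 ± 1.88 to 0.451 ± 0.146 CPM, a change of -2.60 ± 0.56 (edgeR adjusted p = 0.0103). Bank1 fell by 2.38 ± 0.53. The plasma cell list held 9 measured members, since the table had no antibody chain segments, and did not pass (camera adjusted p = 0.888). Prdm1 was its lower member at -1.08 ± 0.13 and Txndc5 its higher one at 0.59 ± 0.13, the same counts adjusted over the list alone. Tnfrsf17 at 1.10 ± 0.43 passed without DSS 2 (edgeR adjusted p = 0.0468) and with limma-voom (0.0336). Of the 8 measured mast cell and eosinophil genes, Il5ra was lower at -2.22 ± 0.64, and 0 were adjusted over the list alone (camera adjusted p = 0.974). It was lost without DSS 1, DSS 3, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (edgeR adjusted p = 0.0595 to 0.0811). Kit at 0.47 ± 0.18 passed in 5 of 22 alternatives, among them without DSS 2 (0.0181). Cpa3 was at -0.81 ± 0.35, or -0.54 without DSS 4. The smooth muscle and posterior Hox means differed in these libraries by -0.94 and -1.79. Beside the muscle score the macrophage, dendritic cell and B cell scores differed by -0.066, -0.081 and -0.91 (exact two-sided permutation p = 0.743, 0.771 and 0.143).

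Interferon-stimulated genes of the type I response were higher as a list by camera, but not by fry. Of 25 measured members 6 were higher and 0 lower over all genes, 1 higher adjusted over the list alone, and the median was 0.62 (camera adjusted p = 1.10e-04; fry adjusted p = 0.163; adjusted p = 0.594 with an estimated correlation). The scores of the libraries overlapped (exact two-sided permutation p = 0.114, n = 4 each). Oas3, an antiviral oligoadenylate synthetase gene (chromosome 5, 120753098 to 120777684), rose from 16.5 ± 3.90 to 65.2 ± 30.2 CPM, a change of 1.98 ± 0.33 (edgeR adjusted p = 0.00466). Irf7, the master transcription factor of this response, rose by 1.32 ± 0.36 and Ifi44 by 1.46 ± 0.42. Irf7 was lost without DSS 1 (edgeR adjusted p = 0.0585), DSS 3 (0.0530), DSS+AP 1 (0.0550) or DSS+AP 3 (0.0714), and Ifi44 without DSS 1, DSS 3, DSS+AP 1 or DSS+AP 3 (0.0584 to 0.0691). Over all alternatives, covariates included, the smallest rises were 0.085 for Irf7, 1.11 for Ifi44 and 1.49 for Oas3. The list of interferon-gamma response and MHC class II genes did not pass (median -0.13; camera adjusted p = 0.764), with 2 higher and 1 lower of 25, or 1 and 1 adjusted over the list alone. It passed as higher with the smooth muscle score (median 0.43; camera adjusted p = 2.78e-05) or Hox position (0.24; 0.00237) as a covariate. Gbp5, an inflammasome-related GTPase gene, fell by 1.66 ± 0.36, whereas Irgm1 rose by 0.71 ± 0.18 and B2m by 0.58 ± 0.17. B2m was lost without DSS 4 (edgeR adjusted p = 0.0706), DSS+AP 1 (0.0582) or DSS+AP 3 (0.0823). Smooth muscle and posterior Hox means differed by -0.94 and -1.79 in the same libraries.

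Stem cell genes were higher and genes of regenerating epithelium lower in DSS+AP colon. Cell cycle genes were higher by camera but not by fry. Stem and progenitor genes were higher in 10 and lower in 0 of 17 members, 11 higher adjusted over the list alone, with a median of 0.62 (camera adjusted p = 3.43e-06; adjusted p = 0.407 with an estimated correlation). Beside Lgr5 at 2.73 ± 0.55, the Wnt target Axin2 (chromosome 11, 108917828 to 108950783) rose from 9.25 ± 4.33 to 28.2 ± 2.19 CPM, Ephb3, a guidance receptor gene of the crypt base, by 1.02 ± 0.13 (edgeR adjusted p = 0.00321), and Hopx by 1.17 ± 0.23. Cell cycle genes were higher in 9 of 26 members, 19 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 2.04e-07; fry adjusted p = 0.0707; adjusted p = 0.488 with an estimated correlation; exact p of the score = 0.0571). The mitotic kinase gene Plk1 rose by 0.71 ± 0.13, Cenpf by 0.84 ± 0.24 and the replication licensing gene Mcm2 by 0.89 ± 0.26. Cenpf and Mcm2 were both lost without DSS 4 (edgeR adjusted p = 0.0713 and 0.0879), DSS+AP 1 (0.0520 and 0.0506), DSS+AP 2 (0.0565 and 0.0660), DSS+AP 3 (0.0596 and 0.0698) or DSS+AP 4 (0.0572 and 0.0563). Fetal-like and regenerating epithelium genes fell in 11 of 17 members, also 11 adjusted over the list alone, at a median of -0.97 (camera adjusted p = 3.50e-04; adjusted p = 0.407 with an estimated correlation). Ereg, which encodes the growth factor epiregulin (chromosome 5, 91074617 to 91093649), fell from 168 ± 43.2 to 42.3 ± 14.3 CPM, and the interleukin 1 receptor antagonist gene Il1rn by 1.76 ± 0.26. Smooth muscle and posterior Hox means were lower in these libraries by -0.94 and -1.79.

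Goblet cell genes did not pass as a list (median 0.31; camera adjusted p = 0.0569), with 4 higher and 1 lower of 20, or 3 and 0 adjusted over the list alone. It passed as higher without DSS 3 (camera adjusted p = 0.0220), DSS 4 (0.0231), DSS+AP 1 (0.0453) or DSS+AP 3 (0.0395), and with Hox position (0.0192) or the anterior Hox score (0.0492) as a covariate. Spdef, the transcription factor of goblet cell maturation, rose by 0.98 ± 0.23 (edgeR adjusted p = 0.0146), Agr2, a disulfide isomerase gene needed for mucin assembly, by 0.75 ± 0.16 and Creb3l1 by 0.67 ± 0.14. Colonocyte genes went both ways, 3 higher and 3 lower of 28, or 2 and 1 adjusted over the list alone, with a median of 0.02 and a mean of -0.32 (camera adjusted p = 0.486). Krt20 rose by 0.60 ± 0.14 and the microvillus gene Vil1 by 0.40 ± 0.10, while the chloride channel accessory gene Clca4b fell by 2.75 ± 0.71. Vil1 was lost without DSS 4 or DSS+AP 3 (edgeR adjusted p = 0.0585 and 0.0525), and Clca4b without DSS 3, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (0.0525 to 0.0598). Of 24 junction genes 2 were higher and 6 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.687). Cldn1, a claudin gene, fell from 10.5 ± 4.95 to 0.948 ± 0.461 CPM (edgeR adjusted p = 0.00371), Jam3 by 1.10 ± 0.17 and Jam2 by 0.99 ± 0.16. Of 21 enteroendocrine and tuft cell genes 4 were lower, also 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.622, direction down, median 0.02). It passed as lower with the smooth muscle score (median -0.60; camera adjusted p = 0.0109) or Hox position (-0.45; 0.0281) as a covariate. Ptgs1 was at -0.74 ± 0.12, Alox5ap at -1.95 ± 0.36 and the tuft cell kinase gene Dclk1 at -0.44 ± 0.10, which was lost without DSS+AP 1 (edgeR adjusted p = 0.0636). The smooth muscle and posterior Hox means were lower in the DSS+AP libraries, by -0.94 and -1.79.

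Genes of the gut wall beneath the epithelium were lower in DSS+AP. All 23 neuron and glia genes were lower, also 23 adjusted over the list alone, with a median of -1.80 (camera adjusted p = 2.11e-11; adjusted p = 0.407 with an estimated correlation). Gfap, the intermediate filament gene of enteric glia (chromosome 11, 102887336 to 102897200), fell from 21.2 ± 8.28 to 2.85 ± 1.39 CPM, the neuronal tubulin gene Tubb3 by 2.18 ± 0.29 and the synaptic gene Snap25 by 1.59 ± 0.19. The endothelial list was lower in all 21 members, also 21 adjusted over the list alone, at a median of -1.28 (camera adjusted p = 2.01e-09; adjusted p = 0.407 with an estimated correlation), with the junction genes Cdh5 at -1.61 ± 0.22 and Pecam1 at -1.22 ± 0.16 and the adhesion molecule gene Vcam1 at -1.64 ± 0.24. Matrix and matrix protease genes fell in 25 of 26 members, also 25 adjusted over the list alone, at a median of -1.69 (camera adjusted p = 8.43e-09; adjusted p = 0.456 with an estimated correlation). Mmp2, which encodes gelatinase A (chromosome 8, 92827290 to 92853421), fell from 194 ± 43.3 to 77.2 ± 8.66 CPM, the basement membrane collagen gene Col4a2 by 1.73 ± 0.28 and the collagen cross-linking gene Lox by 2.09 ± 0.35. The remaining member, the epithelial protease gene Mmp7, rose by 1.98 ± 0.52 and was lost without DSS 3 or DSS+AP 4 (edgeR adjusted p = 0.0557 and 0.0574). Fibroblast genes were lower in 14 of 20 members, also 14 adjusted over the list alone, at a median of -0.87 (camera adjusted p = 2.28e-05; adjusted p = 0.448 with an estimated correlation), with the proteoglycan genes Dcn at -1.35 ± 0.18 and Lum at -1.18 ± 0.16 and with Pdgfra at 179 ± 34.3 and 77.5 ± 5.40 CPM. Smooth muscle genes were lower in 19 of 21, 20 adjusted over the list alone, at a median of -0.92 (camera adjusted p = 3.41e-07; adjusted p = 0.456 with an estimated correlation). Myocd, the master regulator of smooth muscle genes, fell by 0.94 ± 0.16 beside a fall of -1.79 in the mean of posterior Hox genes, Myl9 by 0.83 ± 0.15 and Csrp1 by 1.10 ± 0.20. Erythrocyte genes were lower in 6 of 7, also 6 adjusted over the list alone, at a median of -1.96 (camera adjusted p = 4.56e-04; adjusted p = 0.407 with an estimated correlation). Alas2, the haem synthesis gene of red cells, fell by 2.13 ± 0.31, and the beta globin genes Hbb-bs by 2.02 ± 0.29 and Hbb-bt by 1.96 ± 0.33, close copies whose split is uncertain. Of 17 adipocyte genes Plin4 was lower at -1.15 ± 0.36 and 0 were adjusted over the list alone (camera adjusted p = 0.974, direction up, median -0.08). It was lost without DSS 2, DSS 3, DSS 4, DSS+AP 1, DSS+AP 2 or DSS+AP 4 (edgeR adjusted p = 0.0588 to 0.106). Cd36 at -0.90 ± 0.31 passed in 5 of 22 alternatives, among them without DSS+AP 3 (0.0296). Thrsp at 1.24 ± 0.53 passed without DSS+AP 1 (0.0235) and with DESeq2, and was at 0.76 without DSS+AP 3. With the smooth muscle score as a covariate the adipocyte list passed as lower (median -1.22; camera adjusted p = 0.0111).

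Skeletal muscle and foreign-tissue lists had too few measured members for a set test, 4 and 3. Acta1 was the lower member of the first at -1.28 ± 0.34, also adjusted over the list alone, and was lost without DSS+AP 4 (edgeR adjusted p = 0.0519), with Eno3 at -0.66 ± 0.35 (-0.14 without DSS 4) and Ckm at -0.33 ± 0.25 (-0.52 to -0.19 without 1 library). The keratin gene Krt14 fell in the second by 1.96 ± 0.40, also adjusted over the list alone, at 0.789 ± 0.168 and 0.197 ± 0.105 CPM, with Sis at 2.06 ± 1.16, which passed with the anterior Hox score as a covariate (0.0116), and Mttp at -0.22 ± 0.31 (-0.51 to -0.031 without 1 library).

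Heat shock and immediate early genes fell, with 13 lower and 2 higher of 25, 18 and 2 adjusted over the list alone, and a median of -0.48 (camera adjusted p = 4.57e-04; adjusted p = 0.407 with an estimated correlation). The phosphatase gene Dusp1 (chromosome 17, 26505591 to 26508472) fell from 47.3 ± 5.33 to 17.5 ± 2.18 CPM, Egr2 by 1.54 ± 0.27 and Hspa1a by 1.34 ± 0.25, a near-identical copy of Hspa1b and therefore uncertain. The smooth muscle and posterior Hox means fell in the same libraries by -0.94 and -1.79. Beside the muscle score the heat shock and immediate early score differed by 0.38 (exact two-sided permutation p = 0.143, n = 4 each). Xenobiotic and bile acid response genes did not pass as a list (median 0.66; camera adjusted p = 0.0569), with 4 higher and 2 lower of 24, or 3 and 2 adjusted over the list alone. They passed as higher without DSS 3 (camera adjusted p = 0.0152) or DSS+AP 2 (0.00293) with a minimum of 1 CPM in 4 libraries (0.0375) and with the anterior Hox score as a covariate (0.0149). With the smooth muscle score as a covariate they passed as lower (median -0.69; 0.0388). Their scores were 4.05 to 4.35 in DSS 1, DSS 4 and DSS+AP 2 and 5.22 to 5.70 elsewhere, and the same 3 libraries had low anterior Hox means (1.07 to 1.24 against 2.88 to 3.33). Gstm3, a glutathione transferase gene, rose from 12.0 ± 3.43 to 27.5 ± 4.17 CPM, whereas Cyp1b1 fell by 2.28 ± 0.39 and the aryl hydrocarbon receptor gene Ahr by 0.56 ± 0.12, the last lost without DSS+AP 1 (edgeR adjusted p = 0.0543). The fatty acid oxidation list did not pass (median 0.20; camera adjusted p = 0.233). It passed as higher without DSS+AP 2 (0.0113) and as lower with the smooth muscle score as a covariate (median -0.53; 9.69e-04). It had 1 higher and 3 lower of 24, 0 and 3 adjusted over the list alone. The lower ones were Angptl4 at -2.12 ± 0.40, the lipid droplet gene Plin2 at -0.76 ± 0.16 and Acadl at -0.34 ± 0.08, lost without DSS 4, DSS+AP 1 or DSS+AP 4 (edgeR adjusted p = 0.0526, 0.0741 and 0.0565). Of 18 clock genes Nfil3 fell by 1.66 ± 0.21 and Ciart rose by 0.93 ± 0.28, 0 higher and 1 lower were adjusted over the list alone, and the list did not pass (camera adjusted p = 0.609) but was lower with the smooth muscle score as a covariate (median -0.45; 0.0231). Ciart was lost without DSS 1, DSS 3, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (edgeR adjusted p = 0.0510 to 0.0901), and Per2 at 0.32 ± 0.13 passed without DSS+AP 3 (0.0455) or the low-count filter (0.0427). Of 22 unfolded protein response genes Ero1l was lower at -0.42 ± 0.12 and 0 were adjusted over the list alone (camera adjusted p = 0.974, direction down, median 0.01). The list passed as higher with the smooth muscle score (median 0.38; camera adjusted p = 0.00200) or Hox position (0.25; 0.00138) as a covariate. Ero1l was lost without DSS 2, DSS 4, DSS+AP 1, DSS+AP 3 or DSS+AP 4 (edgeR adjusted p = 0.0662 to 0.117). Atf4 at 0.22 ± 0.08 passed in 5 of 22 alternatives, among them without DSS 2 (0.0482) or DSS+AP 4 (0.0391). Herpud1 at -0.42 ± 0.15 passed in 3 of 22, among them without DSS 2 (0.0488), and was at -0.24 without DSS 4.

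Some lists had few members past the test in 1 direction, and those the naming rule did not take are given here, chosen after their values were seen. Higher were the chemokine gene Ccl25 at 0.84, the tryptophan-degrading enzyme gene Ido1 at 0.75, the T cell co-receptor gene Cd8a at 1.30, the claudin genes Cldn2 at 1.40 and Cldn15 at 0.83 and the fatty acid binding protein gene Fabp2 at 1.28. The detoxification gene Nqo1 at 0.89, the transporter genes Abcc3 at 0.59 and Slc51b at 0.97, the mitochondrial chaperone genes Hspd1 at 0.73 and Hspe1 at 0.63, Ceacam1 at 0.39 and the goblet cell stress sensor gene Ern2 at 0.52 were higher as well. Lower were the proton pump gene Atp12a at -4.97, the serum amyloid gene Saa1 at -2.10, the trefoil peptide gene Tff3 at -0.84 and the peptide hormone gene Pyy at -1.33. Without DSS 1, edgeR no longer called Abcc3, Atp12a, Ccl25, Cd8a, Ceacam1, Cldn15, Cldn2, Ern2, Fabp2, Ido1, Nqo1, Saa1 and Tff3 (adjusted p = 0.0510 to 0.0976). Leaving out DSS 3 ended the calls of Abcc3, Atp12a, Ccl25, Ceacam1, Cldn15, Fabp2, Hspd1, Nqo1 and Saa1 (edgeR adjusted p = 0.0527 to 0.0838). Without DSS 4, edgeR no longer called Abcc3, Atp12a, Ccl25, Cd8a, Ceacam1, Cldn15, Ern2, Hspd1, Ido1, Nqo1, Pyy, Saa1, Slc51b and Tff3 (adjusted p = 0.0526 to 0.116). Leaving out DSS+AP 1 ended the calls of Abcc3, Atp12a, Ccl25, Cd8a, Ceacam1, Cldn2, Fabp2, Hspd1, Ido1, Nqo1, Pyy, Saa1 and Tff3 (edgeR adjusted p = 0.0520 to 0.114). Without DSS+AP 2, edgeR no longer called Ern2, Ido1 and Tff3 (adjusted p = 0.0591 to 0.0971). Leaving out DSS+AP 3 ended the calls of Abcc3, Atp12a, Ccl25, Cd8a, Ceacam1, Cldn15, Cldn2, Ern2, Fabp2, Hspd1, Nqo1, Pyy, Saa1, Slc51b and Tff3 (edgeR adjusted p = 0.0505 to 0.118). Without DSS+AP 4, edgeR no longer called Abcc3, Atp12a, Ccl25, Cd8a, Ceacam1, Cldn15, Cldn2, Ern2, Fabp2, Nqo1, Pyy, Saa1 and Tff3 (adjusted p = 0.0502 to 0.106). The Hspe1 call held without each library. Tff3 was at -0.47 without DSS 4.

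**Figure D2:**
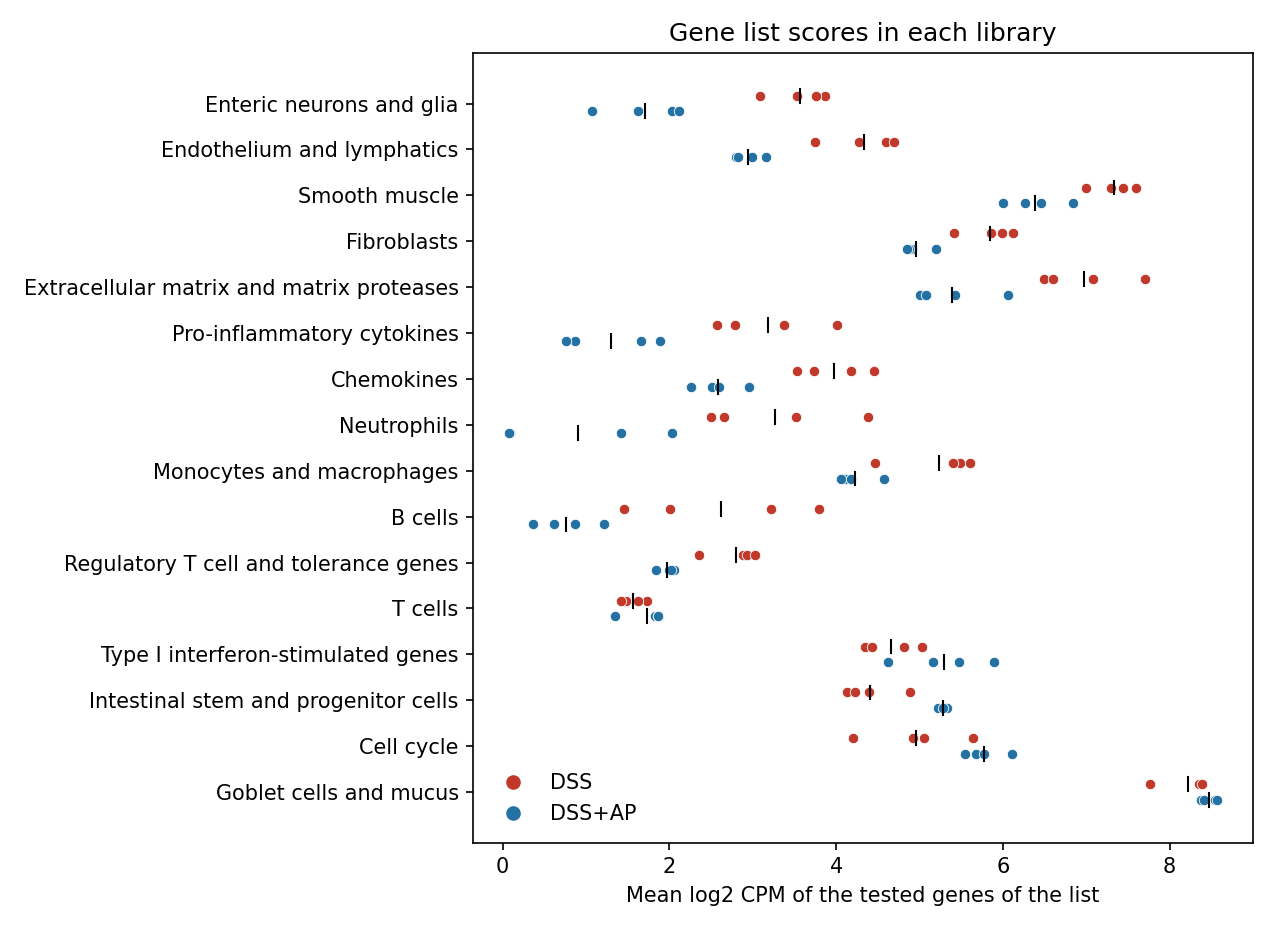
Mean log2 CPM of the tested members of 16 fixed gene lists, with 1 point per library, DSS in red and DSS+AP in blue, and a bar at each group mean. The neuron and glia scores of the 4 DSS+AP libraries all lie below those of the 4 DSS libraries, while T cell scores overlap.

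The first principal component of the 500 most variable genes held 73.2% of their variance and separated the groups, at -23.4 ± 17.8 in DSS and 23.4 ± 16.7 in DSS+AP (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). Without any 1 library other than DSS+AP 2 the difference in means was 42.6 to 53.9 with an exact p of 0.0571. DSS 2 at -3.26 and DSS+AP 2 at 0.0995 lay nearest its middle. Across genes DSS 2 had Spearman correlations of 0.988 with DSS+AP 1 and 0.988 with DSS+AP 4. Within its own group they were 0.989 with DSS 3, 0.983 with DSS 1 and 0.977 with DSS 4. Hox genes, whose expression marks position along the gut, differed between the libraries. The mean of 5 posterior Hox genes was 3.13 ± 0.699 log2 CPM in DSS and 1.34 ± 0.684 in DSS+AP (n = 4 each, exact two-sided permutation p = 0.0286), while that of 11 anterior Hox genes was 2.15 ± 1.06 and 2.63 ± 1.06 (exact p = 0.629). Hoxb13, a gene of the hindgut's end picked after its values were seen, ranged from 4.12 to 123 CPM in DSS and from 0 to 13.1 CPM in DSS+AP, a change of -3.89 ± 1.36 that did not pass (edgeR adjusted p = 0.0608) but did in 4 of 22 alternatives, among them without DSS 2 (-4.21; 0.0402) or DSS+AP 2 (-7.30; 0.0101). It held 58.1% of the difference in the posterior mean. The other 4 genes had edgeR log2 fold changes of -0.72 to -0.12 (edgeR adjusted p = 0.428 to 0.939). In mean log2 CPM, the measure of the score, they differed by -1.92 to -0.069. Without Hoxb13 the posterior mean differed by -0.94 (exact p = 0.0857). Library DSS 4 also held transcripts of pancreatic enzymes that were at 8 estimated counts or fewer each in the other libraries, among them 143065 estimated counts of Amy2a5 and 23305 of Ctrb1. Without DSS 4, 525 genes were higher and 2089 lower, 2589 of them shared with the calls from all libraries. With posterior minus anterior Hox scores as a covariate, edgeR called 30 genes higher and 206 lower, 230 of them shared. With the smooth muscle score as a covariate it called 0 genes, with 911 higher and 913 lower at an unadjusted p under 0.05, and limma-voom called 0. Of the 19 lists called without it, 8 stayed called with the muscle score: neuron and glia, endothelial, fibroblast, erythrocyte, heat shock, stem cell, cell cycle and type I interferon genes. The other 11 were lost, among them cytokine, chemokine, tolerance, neutrophil, macrophage, dendritic cell, B cell, matrix and regenerating epithelium genes (camera adjusted p = 0.0819 to 0.775).

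**Figure D3:**
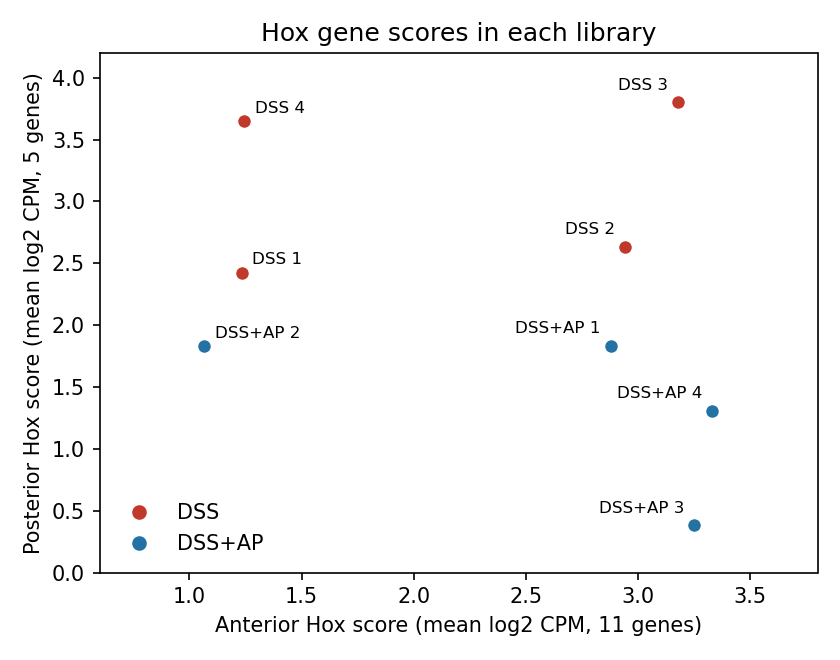
Mean log2 CPM of posterior Hox genes against that of anterior Hox genes, with 1 labelled point per library, DSS in red and DSS+AP in blue. The lowest posterior score among DSS libraries is 2.43 and the highest among DSS+AP libraries is 1.83.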

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

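Of the tests below, those of the follicle and wall explanations, of the Hox scores without Hoxb13 and of the other groupings of libraries were chosen only after the results were seen, and the covariates and the Hox genes were chosen after seeing the data, although the bounds for both Hox tests were written before their values were known. Any grouping of 4 and 4 libraries can give calls by chance, so the fits were repeated for all 35 groupings. For genes, the real grouping gave 4262 and the highest other 0. At an unadjusted p under 0.05 edgeR gave 6249 against at most 4088. Only 1 of the 35, the real one, was as large, the smallest share that 35 groupings allow. Chance is therefore unlikely for genes but not excluded, and the other groupings mix both groups, which widens their error and lowers their counts. For gene lists chance cannot be excluded: the real grouping gave 19 lists and the highest other 24, with 13 of 35 as large.

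Cytokine, neutrophil, neuron, fibroblast and smooth muscle genes fell together, and a smaller share of the muscular wall in the DSS+AP pieces is a candidate explanation. It would leave no difference once the smooth muscle score is subtracted or used as a covariate. For fibroblasts little was left by subtraction (log2 0.058, exact two-sided permutation p = 0.629, n = 4 per group), but with the covariate the list stayed called (median -0.40; camera adjusted p = 0.0267). The differences left for macrophage, dendritic cell and regenerating epithelium genes were -0.066, -0.081 and -0.052 (exact p = 0.743, 0.771 and 0.771), though the last are not of the wall. For tolerance genes 0.12 was left (exact p = 0.486). With the covariate all of these lists lost their calls (camera adjusted p = 0.775, 0.139, 0.125 and 0.166). Both measures thus go with the explanation for them, and a fall of their own was not shown. Neuron and glia genes fell further than muscle genes, by -0.91 (exact p = 0.0286, the smallest possible; 0.0831 adjusted over 32 lists). They stayed called with the covariate (median -0.83; camera adjusted p = 5.39e-05). That call rests on camera's preset correlation, whereas the correlation estimated for this list without the covariate was 0.60. The subtraction takes a smaller wall to lower both lists by the same log2 amount, which was not tested. Muscle share as the whole cause of the neuron and glia fall is therefore not excluded. Neutrophil genes also fell further by subtraction, by -1.42 (exact p = 0.0286; 0.0831 adjusted), but with the covariate their median went from -2.39 to -0.22 and the call was lost (camera adjusted p = 0.725). For cytokines -0.95 was left (exact p = 0.0571), and -0.84 with the covariate (camera adjusted p = 0.125). For fibroblast, neutrophil and cytokine genes the muscle share and a fall of their own cannot be told apart, since the measures disagree or the spread is too wide. With the muscle score as a covariate the fold changes of the called genes kept a median of 0.579 of their size (quartiles 0.335 and 0.902), SEs grew 2.02 times, and edgeR called 0 genes (limma-voom 0; 911 higher and 913 lower at an unadjusted p under 0.05), so the calls ended through smaller folds and wider errors. Treatment with the bacterium, which could change the wall itself, was not tested apart from it.

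B cell genes fell, and lymphoid follicles present in some of the DSS pieces are a candidate explanation. Their score varied 2.07 times as much among the 4 DSS libraries as that of macrophage genes (ratio of SDs), as uneven follicles would give. Adipocyte and neutrophil genes varied nearly as much there (SDs of 1.04 and 0.871 against 1.07), so the spread does not single out follicles. The 4 DSS scores were nevertheless all above the 4 DSS+AP scores in the plot of list scores. A loss of B cells with the bacterium stays open, untested.

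Stem cell, matrix and inflammation genes differed between groups together with Hox genes, and pieces taken from different positions along the colon are a candidate explanation. The posterior minus anterior Hox score was lower in DSS+AP by -2.27 (exact two-sided permutation p = 0.0857, n = 4 per group), and the posterior score alone by -1.79 (exact p = 0.0286), which may also reflect stroma, since -0.85 of it was left beside the muscle score (exact p = 0.114). Hoxb13 held 58.1% of that fall, and without it the scores differed by -1.42 and -0.94 (exact p = 0.0857 for each). With the Hox difference as a covariate the called genes kept a median of 0.739 of their fold changes (quartiles 0.605 and 0.901), against a bound of at least 0.75 set for excluding position, SEs grew 1.39 times and 236 genes were called. With the anterior score alone, which differed by 0.48 between groups (exact p = 0.629), they kept 0.939. Position and treatment cannot be told apart here, because no label gives the position of a piece.

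Library DSS 4 held pancreatic enzyme transcripts, with 143065 estimated counts of Amy2a5, 23305 of Ctrb1, 14713 of Pnlip, 12711 of Cela2a, 10106 of Cpb1, 9610 of Prss2, 9483 of Cpa1 and 9267 of Cel, while the other 7 libraries had at most 8 of each.

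Of 316 groups of 4 values checked, 21 had 1 library far from the other 3, with a gap above 0.829 of the range, and chance gives about 1 in 20, or 15.8. Far above the others were Muc6 in DSS+AP 2 (23.6 CPM against 5.16 to 6.26), Eno3 in DSS 4 (136 against 46.8 to 54.3), and the mean log2 CPM of unfolded protein response genes in DSS+AP 2 (7.30 against 6.942 to 6.999), of plasma cell genes in DSS 4 (5.15 against 4.39 to 4.45) and of fibroblast genes in DSS+AP 2 (5.195 against 4.85 to 4.90). Far below in DSS 2 were Il7r (3.35 CPM against 6.35 to 6.58), Thy1 (11.5 against 20.01 to 21.51), Fcgr3 (32.2 against 64.1 to 65.7), Ccr7 (2.71 against 8.74 to 10.98), Vcam1 (44.8 against 87.7 to 98.7) and mast cell and eosinophil genes (1.43 log2 CPM against 1.77 to 1.81). Far below in DSS+AP 2 were Nkg7 (2.102 CPM against 3.28 to 3.54), Acta1 (1.87 against 5.14 to 5.88), Alas2 (0.234 against 0.496 to 0.558) and the means of clock genes (4.67 log2 CPM against 4.98 to 5.04), xenobiotic response genes (4.35 against 5.52 to 5.70) and T cell genes (1.35 against 1.83 to 1.87). The remaining low values were Ccr7 in DSS+AP 3 (0.248 CPM against 1.32 to 1.36), Myocd in DSS+AP 4 (4.71 against 5.78 to 5.94), mast cell and eosinophil genes in DSS+AP 1 (1.19 log2 CPM against 1.57 to 1.62) and goblet cell genes in DSS 1 (7.76 against 8.35 to 8.38).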

How the results depend on the processing

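All 21 alternatives set beforehand were run, and 3 covariates and a test against a 1.5-fold change were chosen after seeing the data. Against 1288 genes higher and 2974 lower (69.8% lower), total count scaling gave 767 higher (80.7% lower), no low-count filter 1950 (58.2%), DESeq2 2190 (59.7%) and limma-voom 2410 (59.2%), and scaling moved the median of all genes by at most -0.045. Tested against a 1.5-fold change, which asks for more, 29 were higher and 980 lower. Leaving out 1 library gave 525 (without DSS 4) to 2101 (without DSS 2) higher and 1985 to 3086 lower genes, and 3 to 7 (without DSS+AP 2) higher and 15 to 16 lower lists. Lists higher numbered 1 with fry and 0 with an estimated correlation, which called 0 lower ones too (1 at an unadjusted p under 0.05; fry 15 lower). The libraries were separated by 26.9 over 100 genes (exact p = 0.0857) and by 42.6 to 55.7 without 1 library (exact p = 0.0571, and 0.0286 without DSS+AP 2). Replicate numbers are not said to pair the mice, and the values cannot settle whether they do. Same-numbered deviations correlated at -0.14, -0.45, 0.36 and -0.19, and only number 3 matched best both ways. The replicate block gave 582 higher and 1967 lower genes (2491 shared) with the same 19 lists. The covariates gave 30 higher and 206 lower genes (Hox position), 2152 higher (anterior Hox) and 0 and 0 (smooth muscle; edgeR, 911 and 913 at an unadjusted p under 0.05; limma-voom 0). Of the 19 lists, 8 stayed called with smooth muscle, 18 with Hox position and 19 with the anterior score, and 7, 4 and 2 others were called. For lists, a reversal is of the direction camera or fry gave, and not all medians in brackets changed sign. Directions that reversed were of lists and genes not past the test with all libraries, with exceptions under the muscle covariate. These were the smooth muscle list, Ciart (-0.31), Il5ra (0.15), Nqo1 (-0.32), Abcc3 (-0.25), Ceacam1 (-0.066) and Saa1 (0.0035). The smooth muscle median, with its own score as the covariate, shrank from -0.92 to -0.030 and kept its sign. That covariate also reversed Kit (-0.10), Ckm (0.13), Sis (-3.01), Hoxb13 (1.08), Fkbp5 (-0.44), Sgk1 (-0.36) and the lists of interferon-gamma (0.43), antimicrobial (-0.018), fatty acid oxidation (-0.53), unfolded protein (0.38), clock (-0.45), xenobiotic (-0.69), plasma cell (-0.16), T cell (-0.10) and adipocyte genes (-1.22), as medians. Hox position reversed Eno3 (0.12), Sis (-1.47), Fkbp5 (-0.29), Sgk1 (-0.020) and interferon-gamma (0.24), fatty acid oxidation (-0.22), unfolded protein (0.25), xenobiotic (-0.25), plasma cell (0.15) and adipocyte genes (-0.62), and the anterior score interferon-gamma (-0.041), unfolded protein (0.051), mast cell (-0.068) and adipocyte genes (-0.073). The direction for adipocyte genes also reversed with relative log expression (-0.067), the block (0.16) and fry (-0.085). That for mast cell genes reversed with the block (-0.10). Of these, only the adipocyte median under the block changed sign. Under muscle the antimicrobial, unfolded protein, plasma cell and adipocyte medians kept their sign too. So did the unfolded protein and adipocyte medians under Hox position, and every median listed under the anterior score. Under muscle the reversed interferon-gamma, fatty acid oxidation, unfolded protein, clock, xenobiotic and adipocyte lists passed (camera adjusted p = 2.78e-05, 9.69e-04, 0.00200, 0.0231, 0.0388 and 0.0111), and under Hox position interferon-gamma and unfolded protein (0.00237 and 0.00138). Leaving out 1 library reversed the direction camera gave, with medians, not all of which changed sign, within -0.62 to 0.34 (adipocyte), -0.44 to -0.0018 (plasma cell), -0.017 to 0.20 (clock), -0.11 to 0.17 (enteroendocrine), -0.20 to -0.013 (interferon-gamma), -0.57 to 0.0074 (mast cell), -0.059 to 0.057 (junction) and -0.12 to 0.10 (unfolded protein). Apart from the covariates, the cause was not tested. Depth left Il10 and Ifng untested.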

Other observations

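The lists and tests in this part were chosen only after the results were seen. Genes of cholesterol synthesis and uptake were higher in DSS+AP colon, 19 of 21 measured members at an edgeR adjusted p under 0.05 and 0 lower, with a median log2 fold change of 0.72 (n = 4 mice per group). Hmgcs1, which encodes cytosolic HMG-CoA synthase, rose by 1.14 ± 0.17 (SE), from 261 to 574 CPM, and the squalene epoxidase gene Sqle rose by 0.97 ± 0.15 (edgeR adjusted p = 0.00376 and 0.00412). Both calls held without each library, but not with the smooth muscle score as a covariate (edgeR adjusted p = 0.383 and 0.225), where the folds were not smaller. As a list they passed with camera's preset correlation (p = 4.82e-10) and not with an estimated one (p = 0.103), so higher cholesterol gene expression as a coordinated programme may hold but is not settled by 8 libraries.

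Zbtb16, Tat and Dusp1, targets of the glucocorticoid receptor, fell by 3.76, 1.32 and 1.43 on the log2 scale, and lower receptor activity in DSS+AP colon is a candidate explanation. Of 10 other listed targets 5 were lower and 0 higher, with a median of -0.39 (camera p = 0.198 with an estimated correlation and 0.0227 with the preset one), among them Cebpd at -2.07 ± 0.27 and the metallothionein gene Mt2 at -2.40 ± 0.32. Fkbp5 at 0.26 ± 0.22, which passed without DSS+AP 2 (edgeR adjusted p = 0.0375), and Sgk1 at 0.46 ± 0.33 were not lower, although both are targets too. The smooth muscle and posterior Hox means were lower in the same libraries by -0.94 and -1.79. With the muscle score as a covariate Zbtb16, Tat and Dusp1 were at -3.48, -1.03 and -1.27, not called (edgeR adjusted p = 0.349, 0.383 and 0.383). Cebpd was at -0.90 and Mt2 at -1.14 with it, neither called (edgeR adjusted p = 0.401 and 0.392), and with Hox position both missed narrowly (0.0510 and 0.0589). Corticosterone was not measured, and the question stays open.

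Libraries of both groups differed in anterior Hox genes, with mean log2 CPM of 1.23 in DSS 1, 1.24 in DSS 4 and 1.07 in DSS+AP 2, against 2.88 to 3.33 in the other 5 libraries.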
